A study of Mus musculus with 2 samples.

How the data were processed

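Single-cell RNA sequencing libraries of mouse bone marrow HSCs were analysed, 1 from naive mice and 1 from mice 6 weeks after challenge with Listeria monocytogenes. Per the labels' protocols, marrow was flushed from femora and tibiae, red cells were lysed, and libraries were made with a droplet-based 3' kit of 10x Genomics. Per the submitters' processing notes, Cell Ranger 3.0.2 was run on mm10. The values deposited by the authors are raw UMI counts per gene and barcode, not normalized, for every barcode and 31053 genes. Gene positions came from GENCODE vM21 annotation by gene identifier, with 30934 of 31053 identifiers matched. Sequencing reads were not analysed here.

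Cells were called in each library as barcodes with at least the 99th percentile of the 3000 highest UMI totals divided by 10, which was 2640.4 UMIs in the naive and 2240.2 in the Listeria library and gave 6516 and 4955 barcodes. Barcodes with fewer than 500 genes (9 and 18) or over 10% mitochondrial UMIs (187 and 65) were removed. Doublets were called with Scrublet in scanpy 1.11.5, which marked 1 naive and 0 Listeria cells. At these loads that rate is too low for real doublets, so the caller did not work, and doublets remain. The 6319 and 4872 kept cells held 78.3% and 89.6% of each library's UMIs. The libraries' total depths were 64619150 and 43895966 UMIs, which sets the counting intervals given with the values.

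Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, chosen within each library, gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1 (Python 3.11.15, igraph 0.11.9, scikit-learn 1.9.0), 21 in all. Clusters were named from 16 marker lists fixed before the data were examined. The rule that turned markers into names was completed after seeing the data. A marker counted when at least 10% of the cluster's cells had a UMI of it and its CPM was at least 2 times the first quartile of the clusters, after adding 5 CPM to the quartile. A class was given when it had the largest share of markers counted, at least 3 and at least 50%, and when no other class led among the cluster's 10 leading genes. A T cell name also needed a Cd3 gene in at least 10% of cells, which left cluster 10 unnamed, and a cluster of shallow cells needed a marker of its class among its leading genes. By these rules 17 clusters were named and 4 were not.

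Counts were summed over cells, divided by the library's total over those cells and scaled to 1e6 as CPM, with exact Poisson intervals. Log2 ratios of the Listeria over the naive library have exact intervals from the binomial split of the counts, and shares have Clopper-Pearson intervals. No test across libraries was possible with 1 library per group. Gene lists, 31 in number and fixed before the data were examined, were described by the median log2 ratio of members with at least 10 CPM in either library, by the members over 1.25-fold higher or lower, and by the percentile of the median among 10000 random lists matched on mean CPM in 20 bins. Cell cycle shares counted cells with at least 2 UMIs of a list after thinning to 4031 UMIs, which left out 631 naive and 294 Listeria cells with fewer UMIs. Named genes were the 12 highest and 12 lowest ratios among genes with at least 50 CPM in either library and 200 UMIs over both, leaving out mitochondrial, ribosomal protein, unnamed and sex-linked genes, and up to 4 members of each list. Fos, Atf3, Meg3, Isg15, Lrrfip1 and the genes of other classes were also given where named by this rule in another set of cells or chosen after their values were seen. Free RNA was profiled from barcodes with 1 to 50 UMIs. For its subtraction, its amount was set from haemoglobin and neutrophil granule genes, Mpo among them, in HSC-like and B cell-like cells.

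The ratio and list steps were tested on simulated counts of 3062 genes with planted changes. Intervals held the true value for 96% of 50 genes planted at 2-fold, for 92% of 50 planted at 1.5-fold and for 95.1% of 2862 unchanged genes.

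Alternatives fixed before the data were examined covered cell calling, mitochondrial and doublet filters, clustering, normalization with TMM factors (edgeR 4.0.16) and median-ratio size factors (DESeq2 1.42.0, R 4.3.3), weighting, thinning, list minimums and subtraction of free RNA. Both normalizations moved every ratio by less than 0.1 on the log2 scale. Alternatives chosen after seeing the data were removal of the 5% of cells with the highest doublet scores, HSC-like clusters without any of which over 90% came from 1 library, HSC-like with multipotent-like and in-between clusters, and free RNA from barcodes with 20 to 300 UMIs.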

Results

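Single-cell RNA sequencing was carried out on bone marrow haematopoietic stem cells (HSCs) of wild-type C57BL/6J mice, the cells from which all blood lineages descend. There were 2 libraries, 1 per group. The naive library came from untreated mice, and the Listeria library from mice challenged with the bacterium Listeria monocytogenes and sampled 6 weeks later. An age of 6 to 8 weeks is given for the mice of both groups. Whether it applied at challenge or at sampling is not known here, so an age difference at sampling cannot be excluded. The naive library held 64619150 unique molecular identifiers (UMIs, each marking 1 captured transcript) and the Listeria library 43895966. After filtering, 6319 naive and 4872 Listeria cells were kept, with a median of 7004 and 7220 UMIs and of 2350 and 2462.5 genes per cell. In the 5688 naive and 4578 Listeria cells deep enough to be thinned to 4031 UMIs, the median was 1657 genes in the naive and 1700 in the Listeria library. With 1 library per group no difference has a replicate check, no p-value is given, and every value compares these libraries and not the conditions. All intervals are 95% intervals that cover counting error only. They are exact, except that those of differences in points are approximate and combine the intervals of both shares. The deposited name of the Listeria library refers to a knockout and that of the naive library to wild type. The labels give wild type for both and were followed, but a genotype difference cannot be excluded.

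The first comparison asked which cell types the libraries held. Both were dominated by stem and progenitor cells, and both also held cells with transcripts of single lineages: early B-lineage cells, cells of the megakaryocyte lineage, which makes platelets, and few neutrophil-like, dendritic cell-like, natural killer (NK) cell-like, plasma cell-like and erythroid-like cells. B cell-like cells made up a smaller share of the Listeria library. Megakaryocyte lineage-like cells made up a larger share of it, and so did HSC-like cells. The size and the direction of the HSC-like difference, however, depended on how clusters were drawn and named.

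B cell-like cells (clusters 4 and 7) formed 21.5% of the naive library (20.5% to 22.5%) and 8.09% of the Listeria library (7.34% to 8.89%). Megakaryocyte lineage-like cells (clusters 8, 11 and 13) formed 8.86% (8.17% to 9.59%) of the naive library and 974 of 4872 cells (18.9% to 21.1%) of the Listeria library. When the libraries were clustered again without the genes that differed over 1.5-fold between them, the B cell-like shares were 21.2% and 7.96%, and the megakaryocyte lineage-like shares 10.0% and 21.1%. HSC-like cells (clusters 2, 3, 5 and 15) formed 21.2% (20.2% to 22.2%) of the naive and 38.0% (36.7% to 39.4%) of the Listeria library, and 28.3% and 1949 of 4872 cells (38.6% to 41.4%) without the differing genes. At a coarser clustering the HSC-like shares were 17.3% and 14.6%. Cluster 3 held 1000 Listeria cells and 23 naive cells, and a cluster drawn mostly from 1 library can be that library and not a cell type. Cluster 3 counted 9 of 18 HSC markers, the least that the rule allowed, with 0 among its 10 leading genes. Without cluster 3 the HSC-like share was lower in the Listeria than in the naive library. Cluster 1 held 904 naive and 272 Listeria cells. It counted 10 of 18 HSC markers but stayed unnamed, because another class led among its leading genes. The naming rule, completed after the data were seen, left clusters 1 and 9 between the HSC-like and multipotent-like classes, with 23.6% of naive and 8.46% of Listeria cells. In HSC-like, multipotent-like and these clusters combined, the shares were 53.6% (52.3% to 54.8%) and 60.4% (59.1% to 61.8%), and 52.8% and 59.2% without the differing genes.

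**Figure D1:**
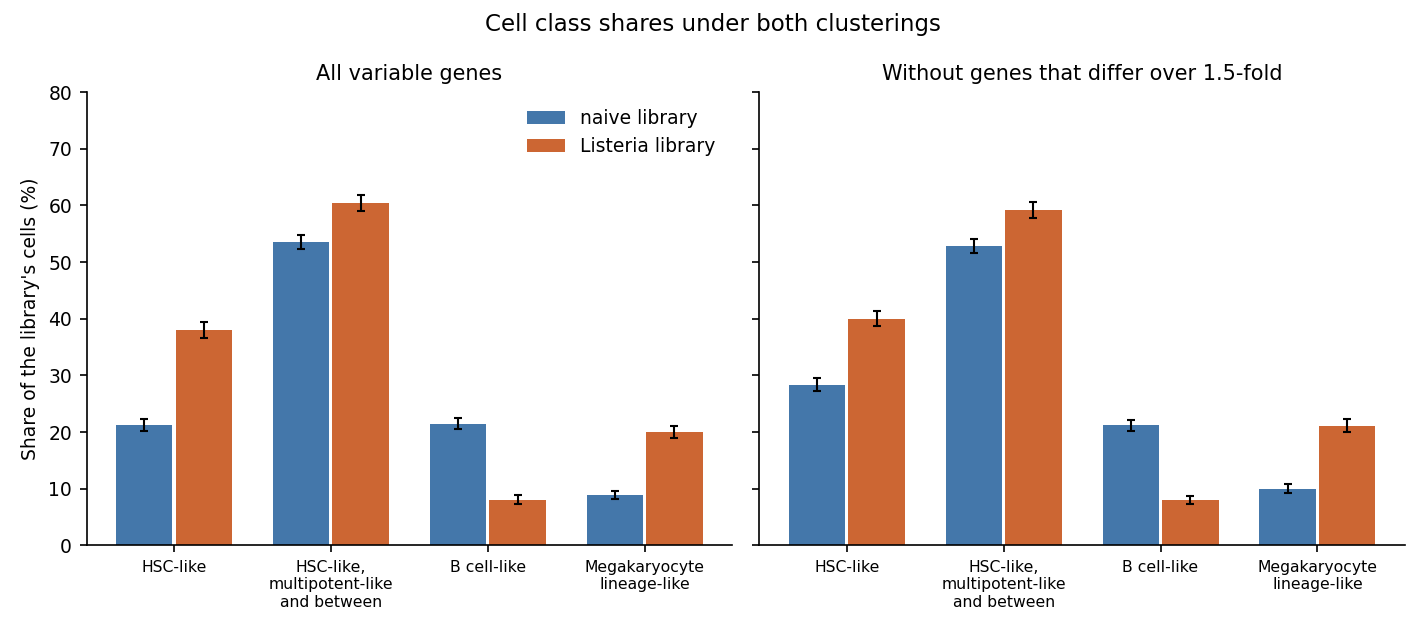
Share of each library's cells (%) in 3 classes and in the HSC-like, multipotent-like and in-between clusters together, with exact 95% intervals, from the clustering on all variable genes (left) and on those without genes that differ over 1.5-fold (right). The B cell-like share was 21.5% in the naive and 8.09% in the Listeria library on the left, and 21.2% and 7.96% on the right.

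Multipotent-like cells, which have begun to leave the stem cell state, formed 8.74% of the naive and 14.0% of the Listeria library (clusters 6 and 12). The clusters went opposite ways, with 289 naive and 615 Listeria cells in cluster 6 and 263 and 65 in cluster 12. Plasma cell-like cells formed 1.47% and 0.903%, NK cell-like cells 1.98% and 1.68%, and neutrophil-like cells 1.19% and 1.77%. The NK cell-like cluster 14 also counted 10 of 12 T cell markers and had Cd3g among its leading genes, so it may hold T cells. A further pair of unnamed clusters, 10 and 16, held 512 naive and 186 Listeria cells. The labels name no sort gate beside HSC, and shares count captured cells, not cells in marrow.

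The second comparison took all kept cells together and asked which transcripts differed between the libraries. Genes of early B cells were lower in the Listeria library. Genes of dividing cells were lower as well, although within the B cell-like and the HSC-like cells they were not. The platelet integrin gene Itga2b and a list of platelet-biased HSC genes were higher. The antiviral gene Rsad2 was higher too, whereas interferon-induced genes as a group were at like levels.

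Vpreb1, part of the surrogate light chain that early B cells carry (mm10 chromosome 16, 16868403 to 16870843), was at 401 CPM (UMI counts scaled to a total of 1e6; 396 to 407) in the naive and 127 CPM (123 to 131) in the Listeria library, a log2 ratio of -1.66 (-1.71 to -1.62). Its partner Igll1 (-1.44), the B-lineage Vpreb3 (-1.66), the B cell receptor component Cd79a (-1.45) and the lymphoid transcription factor Lef1 (-1.43) were lower too. Of 20 measured genes of lymphoid priming, 15 were lower by more than the fold limit set for list members and 0 higher. Their median log2 ratio was -0.64, at percentile 0 of 10000 random lists matched on expression. The list holds B-lineage genes such as Vpreb1 and Igll1, so the smaller B cell-like share bears on this median. In HSC-like cells the list had a mean of 7.26 UMIs per cell in the naive and 7.13 in the Listeria library. Among 44 genes of the G2 and M phases, 31 were lower and 0 higher, with a median of -0.48. Their median was 0.10 within the B cell-like and 0.07 within the HSC-like cells.

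Rsad2, which encodes the antiviral enzyme viperin (chromosome 12, 26442746 to 26456452), was at 34.6 CPM (33.0 to 36.3) in the naive and 89.6 CPM (86.7 to 92.7) in the Listeria library, a log2 ratio of 1.37 (1.29 to 1.46). The share of cells with an Rsad2 UMI was 10.5% and 11.9%, and 2982 of the 3526 UMIs of the Listeria library lay in HSC-like cells, where the ratio was 1.48, and -0.07 without cluster 3. The type I interferon response list as a whole had a median of 0.07, with 5 of 37 genes higher and 7 lower, at percentile 53.4. Ifi27l2a, also interferon-induced, was lower at -1.47. Itga2b, the platelet integrin CD41, was higher at 0.86 (0.77 to 0.94), and the platelet-biased HSC list had a median of 0.45 with 6 of 10 genes higher and 0 lower. Epb41l2, a membrane skeleton protein (1.16), Lrrfip1, a nucleic acid-binding regulator (0.93), and the calcium-binding protein Anxa2 (0.95) were among the highest.

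Several antibody genes were carried mostly by single cells. Ighg3, a heavy chain, had 2856 UMIs in the naive library, of which 2822 came from 1 plasma cell-like cell, against 4 UMIs in the Listeria library. Ighg2c had 1 UMI in the naive library against 2813, of which 2789 came from 1 cell, a log2 ratio of 11.82 with an interval from 9.34 to 17.13. For Igha, the mucosal antibody class, the highest cell held 26.2% of the naive and 73.9% of the Listeria UMIs, and for the light chain Iglc2 50.8% and 41.6%. For Igkc it held 3.35% and 6.11%, and for Ighm 3.32% and 5.45%.

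The third comparison stayed within the HSC-like cells and asked how stem cells differed 6 weeks after infection. Genes switched on within minutes of stimulation or tissue handling, the immediate early genes, were lower in the Listeria library. Genes that mark HSCs, most of which also served to name the clusters, were lower. Single genes such as Mpo and Lgals3 were higher, mainly through cluster 3. Without cluster 3, which was almost wholly from the Listeria library, the genes that mark HSCs had the opposite sign. The other differences named here were smaller without it. Cd53, S100a4, Plac8 and Rsad2, higher with that cluster, had the opposite sign without it. Lower Jund, Klf4, Atf3, Cdkn1a, Rgcc and Meg3 were seen with and without that cluster, but the make-up of the remaining cells differed too. Cluster 2, which has Meg3, Atf3, Cdkn1a and Cxcl10 among its leading genes, held 753 naive and 292 Listeria cells. Jund and Klf4 were lower within each of clusters 2, 5 and 15, Atf3, Cdkn1a and Rgcc within 2 and 5, and Meg3 within 5 and 15.

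Of 33 measured genes of the immediate early and dissociation response, 28 were lower by more than that limit in the HSC-like cells of the Listeria library and 0 were higher. The median log2 ratio was -0.78, at percentile 0 of random lists. Several other classes shared the direction, with -0.51 in the megakaryocyte lineage-like (26 of 32 lower, 0 higher), -0.67 in the myeloid progenitor-like and -0.29 in the B cell-like cells, but it was -0.07 in the multipotent-like and 0.25 in the NK cell-like cells. In HSC-like cells without cluster 3 the median was -0.07, with 5 genes higher and 8 lower. Jund, a subunit of the AP-1 transcription factor (chromosome 8, 70698949 to 70700616), was at 5243 CPM (5196 to 5290) in the naive and 2136 CPM (2110 to 2161) in the Listeria HSC-like cells, a log2 ratio of -1.30, and -0.58 without cluster 3. The transcription factor Klf4 was at -1.49 and then -0.67, the stress-induced Atf3 at -1.19 and then -0.99, and the cell cycle inhibitor Cdkn1a at -1.25 and then -0.95. Rgcc, a regulator of the cell cycle (chromosome 14, 79288756 to 79301645), was at 779 CPM (761 to 798) against 229 CPM (221 to 238), a log2 ratio of -1.77 (-1.83 to -1.70), and -0.83 without cluster 3. The imprinted RNA Meg3 was at -1.45 and -0.82. Fos, another AP-1 subunit, was at -0.34 with cluster 3 and 0.76 without it, a value that includes the difference in make-up: it was at 194 and 202 CPM in cluster 2, 1880 and 2437 CPM in cluster 5, and 1341 and 821 CPM in cluster 15.

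**Figure D2:**
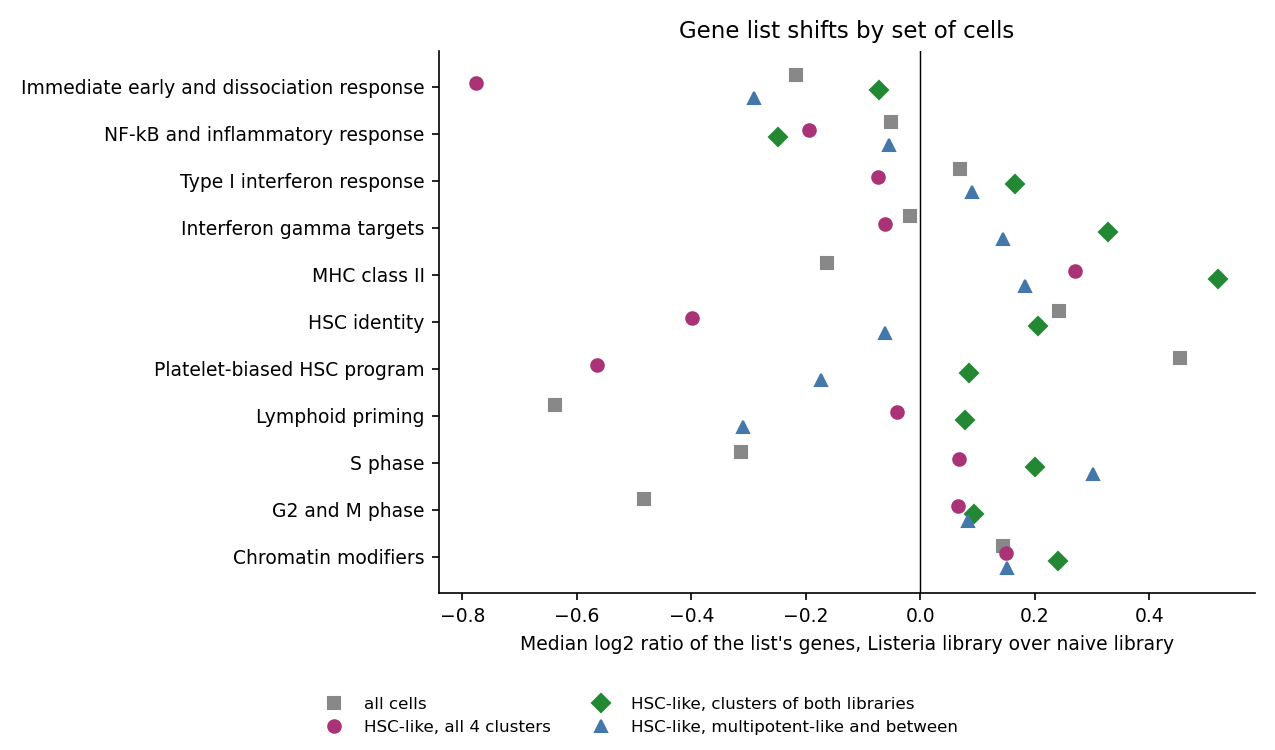
Median log2 ratio (Listeria over naive library, x axis) of the measured genes of 11 lists (y axis) in 4 sets of cells, 1 point per set. The immediate early list lay at -0.78 in all HSC-like clusters and at -0.07 in those of both libraries.

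The HSC identity list, transcription factors and surface proteins typical of stem cells, had a median of -0.40 with 14 of 25 genes lower and 1 higher. Most of these genes are also HSC markers by which clusters were named, and cluster 3 was named with 9 of 18 markers counted. The lower median thus cannot be told apart from which clusters that naming let in. Without cluster 3 its median was 0.21, with 9 higher and 2 lower, and it was -0.06 over HSC-like, multipotent-like and in-between cells together. The platelet-biased list, higher in all cells, had a median of -0.57 in the HSC-like cells with 7 of 13 genes lower and 2 higher, and 0.09 without cluster 3. Mpo, the granule enzyme of myeloid cells (chromosome 11, 87793581 to 87804413), was at 5.16 CPM (3.79 to 6.86) in the naive and 54.2 CPM (50.2 to 58.4) in the Listeria library, a log2 ratio of 3.39 (2.97 to 3.85), from 47 and 677 UMIs. The lectin Lgals3 (3.08) and Anxa2 (2.48) followed. Without cluster 3, Mpo was at 1.07, from 32 and 42 UMIs, Lgals3 at 0.28 and Anxa2 at 0.49. Most Mpo UMIs of the Listeria HSC-like cells thus lay in cluster 3, which held 23 naive and 1000 Listeria cells. Of the 47 naive Mpo UMIs, 32 lay outside cluster 3, so its 23 naive cells carried Mpo as well. The ratio of 3.39 thus mostly reflects that difference in make-up and is no evidence of a rise within cluster 3. At a coarser clustering Lgals3 was at -0.34. The myeloid priming list as a whole had a median of 0.06, with 5 of 11 genes higher and 4 lower. Of 4 neutrophil granule genes 3 were lower and 1 higher, with a median of -0.74 that was 1.76 after subtraction of free RNA. The amount subtracted was set partly from these same genes, so 1.76 is no check on their direction. Over HSC-like, multipotent-like and in-between cells together, Mpo was at 0.65, Lgals3 at 1.81 and Anxa2 at 1.36. The membrane protein Cd53, the calcium-binding S100a4, the myeloid gene Plac8 and Rsad2 were higher in the HSC-like cells, at 1.81, 1.62, 1.58 and 1.48, but were at -0.40, -0.18, -0.25 and -0.07 without cluster 3.

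Interferon-induced genes went both ways in the HSC-like cells. The type I list had a median of -0.07 with 8 of 38 genes higher and 12 lower. Ifitm1, an antiviral membrane protein, was at 1151 CPM in the naive and 577 CPM in the Listeria library. Without cluster 3 its median was 0.17, with 9 higher and 2 lower, while Isg15, a ubiquitin-like interferon target, was at -1.24 and the chemokine Cxcl10 at -1.10. These values include the make-up difference in cluster 2, but Cxcl10 was also lower within each of clusters 2, 5 and 15 and Isg15 within 2 and 5. In the same cells the interferon gamma target list had a median of 0.33 and the MHC class II list, which presents antigen, 0.52, each at a percentile above 99. With cluster 3 these medians were -0.06 and 0.27. Igkc and Ighm, the lowest genes at -2.92 and -2.37, are antibody transcripts that were also found in NK cell-like and megakaryocyte lineage-like cells. The HSC-like class was drawn from the same counts that were compared within it.

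The HSC-like, multipotent-like, in-between and megakaryocyte lineage-like clusters were also split by Fos and Lrrfip1. Clusters 1, 2, 3 and 8 had fewer Fos than Lrrfip1 UMIs, and they held 29.7% (28.5% to 30.8%) of naive and 43.3% (41.9% to 44.7%) of Listeria cells. Of the cells in the clusters that were split, they held 47.5% (45.9% to 49.1%) and 53.8% (52.3% to 55.4%). This grouping was made after the data were seen and does not mark low immediate early transcripts in general, since naive Jund was at 5496 CPM in cluster 2 and 5352 CPM in cluster 5. In cluster 8, Lrrfip1 was at 287 CPM in the naive and 641 CPM in the Listeria library, and in cluster 2 at 316 and 520 CPM. Among clusters with higher Fos it was at 222 and 230 CPM in cluster 6, 176 and 220 CPM in cluster 5, 188 and 233 CPM in cluster 11, and 211 and 334 CPM in cluster 13. Naive Lrrfip1 was at 329 CPM in cluster 12 and 277 CPM in cluster 9, near its levels in clusters 2 and 8.

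**Figure D3:**
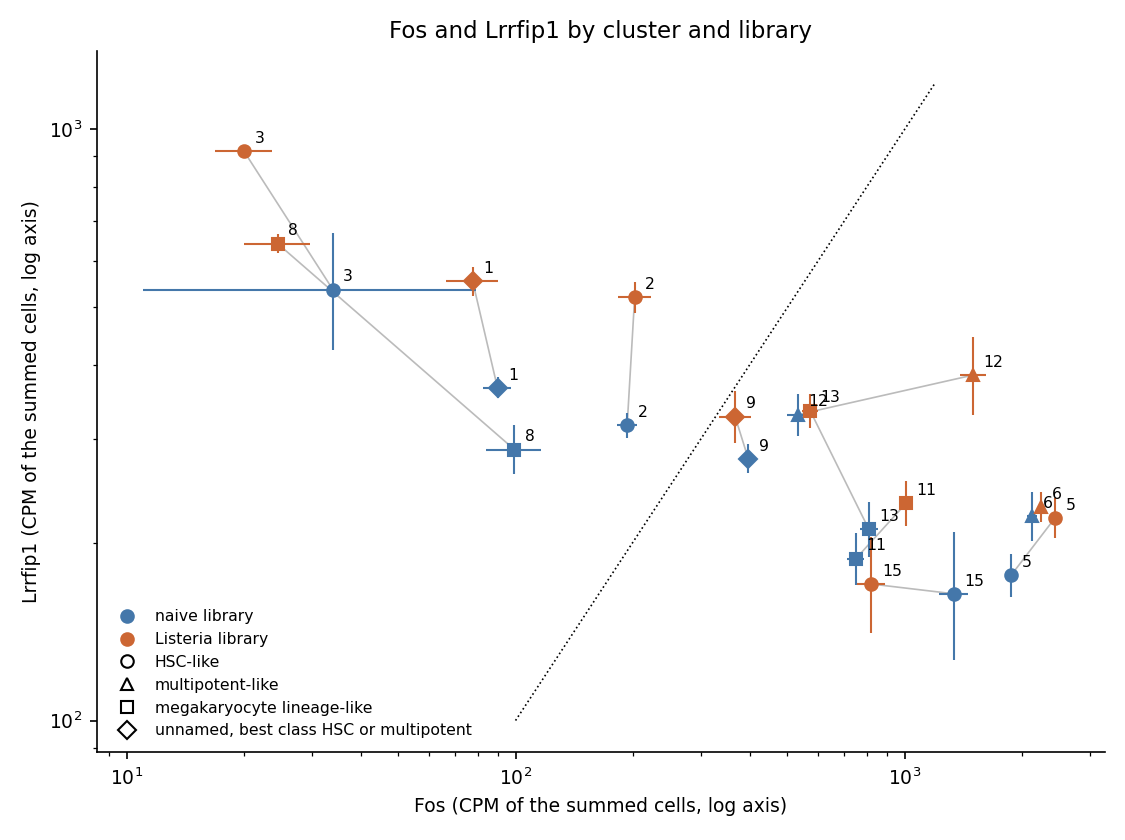
Fos (x axis) and Lrrfip1 (y axis) in CPM on log axes, summed over the cells of each numbered cluster in the naive (blue) and Listeria (orange) library, with exact 95% Poisson intervals and a line joining the libraries. Points left of the dotted line of equal CPM, clusters 1, 2, 3 and 8, had fewer Fos than Lrrfip1 UMIs in the cells of both libraries combined.

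The same comparison was made within the other large classes. B cell-like cells of the Listeria library had higher transcripts of the heat shock protein Hspa1a (1.58), of the translation inhibitor Eif4ebp1 (0.89) and of the amino acid transporters Slc7a1 (0.55) and Slc3a2 (0.54), and lower Lmo2, a haematopoietic cofactor (-1.12). In megakaryocyte lineage-like cells S100a4 (1.72), Epb41l2 (1.66) and Lrrfip1 (1.01) were higher and Rgcc (-1.32) and the antiproliferative gene Btg2 (-1.06) lower. Cluster 8 held 194 of 560 naive and 546 of 974 Listeria cells of this class, so these ratios include a difference in make-up. In multipotent-like cells the B-lineage genes Ly6d (-4.44), Blnk (-3.18) and Ebf1 (-2.79) were lower and the replication genes Mcm5 (1.31) and Mcm3 (1.12) higher. Cluster 12, with 263 naive and 65 Listeria cells, belongs to that class, so its ratios include one as well.

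The cell cycle was also counted cell by cell. Among the 5688 naive and 4578 Listeria cells that could be thinned, 92.4% (91.7% to 93.1%) and 91.3% (90.5% to 92.1%) had at least 2 UMIs from the S phase list, and 98.1% and 98.6% from the G2 and M list. The differences were -1.12 points (-2.20 to -0.041) for the S phase and 0.558 points (0.046 to 1.06) for G2 and M, and both intervals included 0 under several alternatives. Without thinning, in all kept cells, the shares were 96.5% and 95.8%, and 99.5% and 99.5%. Nearly every cell passed, so the measure was near saturation and did not separate cycling from resting cells, and free RNA adds UMIs of these genes to any cell.

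Free RNA, released from broken cells and caught in every droplet, was read from barcodes with few UMIs. Antibody transcripts made up 8605 CPM of barcodes with 1 to 50 UMIs in the naive and 6656 CPM in the Listeria library. Barcodes with 20 to 300 UMIs, a range added after the data were seen, held a mean of 1.68 antibody UMIs in the naive and 0.247 in the Listeria library. HSC-like cells held a mean of 2.48 and 0.394, megakaryocyte lineage-like cells 2.44 and 0.425, and NK cell-like cells 2.65 and 0.963, at median depths of 6438 and 6366, 8512.5 and 8604, and 4045 and 3695.5 UMIs.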

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

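All tests of explanations in this part were chosen after the results they weigh had been seen.

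A signal outside the kept cells differed between the libraries. In barcodes with 1 to 50 UMIs, Gm42418, a gene model that overlaps ribosomal RNA, was at 159530 CPM in the Listeria and 7639 CPM in the naive library, and AY036118, of the same kind, at 4083 and 735 CPM. Haemoglobin transcripts were at 1826 and 1140 CPM, and Elane, a neutrophil enzyme, at 249 and 121 CPM. Lower in the Listeria library were mitochondrial transcripts at 51346 and 131111 CPM, and the B-lineage genes Vpreb1 at 147 and 420 CPM and Ighm at 1637 and 2641 CPM. These are the sets over 1.5 times apart, among 14 sets of which the single genes were chosen after the data were seen, and the cause was not tested. Most of these differences depended on the range: with 1 to 10 UMIs, Gm42418 was at 10212 and 6658 CPM, AY036118 at 894 and 687, haemoglobin at 1568 and 1174, Elane at 151 and 122, mitochondrial transcripts at 131909 and 134944, Vpreb1 at 108 and 422, and Ighm at 2178 and 2646 CPM. With 20 to 300 UMIs, a range added after the data were seen, mitochondrial transcripts were higher in the Listeria library, at 49683 and 17809 CPM. The other sets named here kept their direction there, with Gm42418 at 194970 and 71409 CPM and Vpreb1 at 151 and 303 CPM. The 1 to 50 range held 2943123 UMIs in 606228 barcodes of the Listeria and 1372392 UMIs in 914569 barcodes of the naive library. It thus took in unlike barcodes, and the mitochondrial difference cannot be separated from the choice of range.

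Between classes, the HSC identity list differed in direction. Its median log2 ratio was 0.66 in the multipotent-like and -0.40 in the HSC-like cells, and the difference between classes was not tested. Most genes of the list also served to name the HSC-like clusters. The HSC-like value was 0.21 without cluster 3, 0.22 at resolution 0.5 and 0.0081 with each library clustered separately, and the multipotent-like value includes the make-up of cluster 12, with 263 naive and 65 Listeria cells.

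Lower immediate early transcripts in the HSC-like cells of the Listeria library were weighed first. For Jund and Klf4, different shares of clusters are argued against as the only cause, since Jund was lower in 11 and Klf4 in 10 of 11 progenitor clusters, with intervals apart. Clusters 2, 3, 5 and 15 are the HSC-like ones, and all clusters come from the same 2 libraries. The Klf4 exception was cluster 3, at 136 CPM in the naive and 140 CPM in the Listeria library. It held 1000 of the 1853 Listeria HSC-like cells. For the list as a whole, different shares of clusters stay open as the cause. With the naive clusters weighted to their shares in the Listeria library, its median was -0.065. This rests on 23 naive cells of cluster 3 and on clusters drawn from the same counts. A state that arises only after infection stays open as well, since cluster 3 held 0.364% of naive cells. The handling of 1 library and the earlier infection coincide, however, and so does genotype if the deposited names hold.

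The lower B cell-like share was weighed next. The cell call is argued against, since the Listeria share was still lower at a fixed minimum of 500 UMIs, with a difference of -13.3 points. A purity difference that brought all other classes into the naive library alike is argued against as well, since among the named classes other than the HSC-like, multipotent-like and megakaryocyte lineage-like, B cell-like cells formed 72.9% (70.8% to 74.9%) in the naive and 51.4% (47.8% to 55.0%) in the Listeria library, a difference of -21.5 points. An effect of the earlier infection and a difference in sorting, in 1 animal or in genotype, to which the deposited names refer, cannot be told apart with 1 library per group.

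Antibody transcripts in naive HSC-like cells were weighed last. Whether free RNA accounts for them stays open, because neither range of barcodes that stood for it settles the question. The naive over Listeria ratio of antibody UMIs was 6.29 per HSC-like cell and 6.80 per barcode with 20 to 300 UMIs, so that the cell ratio was 0.925 times the barcode ratio, but that range was added after the data were seen. Per barcode with 1 to 50 UMIs, the range chosen before, the ratio was 0.400, and the cell ratio was 15.7 times as high. Barcodes of that range held fewer UMIs on average in the naive library, so 0.400 is no evidence against free RNA. Those with 20 to 300 UMIs held more on average in the naive library, so 6.80 includes a difference in depth too. As CPM, antibody transcripts were higher in the naive library in both ranges, at 8605 and 6656, and at 11735 and 6001. With 1 to 10 UMIs they were not, at 8555 and 8776 CPM. Droplets that also held an antibody-producing cell are argued against as the main source, since the 5% of naive HSC-like cells with the most antibody UMIs held 27.2% of them.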

How the results depend on the processing

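Chosen after seeing the data were the removal of the 5% of cells with the highest doublet scores, the sets of HSC-like cells without cluster 3 and with multipotent-like and in-between cells, and free RNA from barcodes with 20 to 300 UMIs. A value counted as changed when it left the counting interval of its reported value, or, for a list median, the range that held 95% of medians from resampled counts. No paired analysis was possible because each group has 1 library. The cause of a change was not tested unless stated.

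The B cell-like difference, -13.4 points as reported, kept its direction under all 11 alternatives run and left its interval under 1, a mitochondrial limit of 5% (-16.0). The megakaryocyte lineage-like difference of 11.1 points stayed positive in the 10 alternatives that gave a value. At Leiden resolution 0.5 no cluster was named megakaryocyte lineage-like, so none is given there. Haemoglobin medians within the HSC-like cells were left out because 1 droplet held over 50% of the UMIs. For the other genes with the highest and lowest ratios, 286 of 286 values in all cells kept their direction, and 427 of 436 in the HSC-like cells. Of the other list medians, 169 belonged to lists whose reported median passed the fold limit, and 163 of these kept their direction. These genes and lists were picked for large values, which alternatives that rescale every ratio alike could hardly reverse. TMM factors, for example, moved all-cell ratios by -0.0505. The counts are thus a weak check on direction. All gene reversals in HSC-like cells came from resolution 0.5, from leaving out clusters over 90% from 1 library, or from adding multipotent-like and in-between cells.

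A minimum of 500 UMIs gave differences of 19.1 points for HSC-like cells, 9.18 for HSC-like, multipotent-like and in-between cells together and 9.52 for megakaryocyte lineage-like cells, Mpo at 2.88 and the immediate early list at -0.88. A minimum of 2000 UMIs put Mpo at 2.94.

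A mitochondrial limit of 5% gave 10.9 points for HSC-like and 11.7 for the combined cells, Vpreb1 at -1.76, the G2 and M list at -0.56, Rgcc at -1.53, Mpo at 1.22, the immediate early list at -0.50 and HSC identity at -0.24. Without that filter the shares differed by 10.5 points (HSC-like), 8.84 (combined) and 8.27 (megakaryocyte lineage-like), Mpo was at 1.96, the immediate early list at -0.67, HSC identity at -0.27, and the share of cells with G2 and M UMIs differed by 0.0139 points.

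With doublets kept, 6320 instead of 6319 naive cells were clustered and the Listeria cells were the same. The megakaryocyte lineage-like difference was nevertheless 9.53 points. A shift of this size can thus come with redrawing the clusters alone, which the counting intervals of shares do not cover. Removing the highest 5% of doublet scores gave 5.95 points for HSC-like and 9.56 for megakaryocyte lineage-like cells, Rsad2 at 1.46 in all cells, Rgcc at -1.49, Mpo at 0.76, the type I interferon list at -0.0027, the immediate early list at -0.43 and HSC identity at -0.14.

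Clustering changed several HSC-like results. At resolution 0.5 the HSC-like share was lower in the Listeria library (-2.67 points) and the combined share higher by 16.3 points. Rgcc was then at -0.94, Mpo at 0.86, the immediate early list at -0.11 and the type I interferon list at 0.18. Signs reversed for Lgals3 (-0.34), Cd53 (-0.16), S100a4 (-0.49), Plac8 (-0.24), HSC identity (0.22), the platelet-biased list (0.10) and erythroid priming (0.17). Resolution 2 gave 4.53 points for the combined cells, Rgcc at -1.66 and the immediate early list at -0.64.

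Without cell cycle genes the HSC-like difference was 21.1 points and the megakaryocyte lineage-like 9.77, with Rgcc at -1.90, the immediate early list at -1.01 and HSC identity at -0.48. With each library clustered separately the differences were 8.04 (HSC-like), 1.79 (combined) and 12.5 points (megakaryocyte lineage-like), with Rgcc at -1.15, Mpo at 1.70, the type I interferon list at 0.13, the immediate early list at -0.33 and HSC identity, reversed, at 0.0081. Without genes that differ over 1.5-fold the HSC-like difference was 11.7 points, Rgcc was at -1.68, Mpo at 2.86, the immediate early list at -0.58 and HSC identity at -0.29.

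Without cluster 3 Rgcc was at -0.83, Mpo at 1.07, the type I interferon list at 0.17 and the immediate early list at -0.073. Reversed were Cd53 (-0.40), S100a4 (-0.18), Plac8 (-0.25), Rsad2 (-0.070), HSC identity (0.21), the platelet-biased list (0.086) and erythroid priming (0.13). With multipotent-like and in-between cells added, Rgcc was at -1.09, Mpo at 0.65, the type I interferon list at 0.091, the immediate early list at -0.29 and HSC identity at -0.062, and Plac8 reversed to -0.30.

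TMM factors put Vpreb1 at -1.71 and the G2 and M list at -0.53, median-ratio factors at -1.71 and -0.53, and thinning at -1.75 and -0.53. Weighting cells equally put lymphoid priming at -0.70. List members of at least 50 CPM put lymphoid priming at -0.58, and in HSC-like cells the type I interferon list at -0.23 and HSC identity at -0.24.

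Free RNA subtraction put Mpo at 4.02 and reversed the neutrophil granule list in HSC-like cells to 1.76. With the profile of barcodes with 20 to 300 UMIs these were 5.73 and 2.61, and HSC identity was at -0.44. The amount subtracted was set from haemoglobin and neutrophil granule genes, Mpo among them. The values for Mpo and the granule list are thus what that setting left over, and they check neither result. Antibody transcripts in free RNA of the naive library were at 9880 CPM in barcodes with 1 to 100 UMIs and 11735 CPM in those with 20 to 300. In the Listeria library they were at 8776 CPM with 1 to 10 UMIs and 6001 CPM with 20 to 300. Depth limits the genes with few UMIs, such as Mpo with 47 in the naive HSC-like cells.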

Other observations

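The plasma cell-like cells expressed mainly Ighm. It led the heavy chains in 78 of 93 naive cells, 83.9% (74.8% to 90.7%), and in 34 of 44 Listeria cells, 77.3% (62.2% to 88.5%). Igha led in 7 naive cells and 1 Listeria cell.

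Haemoglobin UMIs in HSC-like cells came almost wholly from 1 droplet per library. It held 5919 of 6101 in the naive and 4820 of 5170 in the Listeria library.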
